A study of Mus musculus with 9 samples.

How the data were processed

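Polyadenylated RNA from the ROC6 murine oral squamous cell line was sequenced as stranded paired-end libraries, per the labels' protocols, in 9 libraries: 3 with a Csmd3 knockout by guide 1, 3 with a knockout by guide 2, and 3 controls. Groups and replicate numbers were taken from the sample titles. The deposited values are FPKM for each gene and library, per the file headers. The submitters' processing notes name cutadapt, FastQC, HISAT2 and StringTie. Their versions, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. FPKM removes the read total, and no counts were used, so depth and counting error are unknown and no count model was fitted. The number of other columns of per-sample values was 0.

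The table held 15620 rows. The 174 rows that share 62 gene symbols were left out, because the column names and values show a guide 1 and a guide 2 table joined by symbol, which crosses records. For Aldoa, 1 row had means of 329, 2.76 and 293 FPKM and another 0.955, 193 and 1.44 FPKM in guide 1, guide 2 and control. Of the 15446 uniquely named genes, 8481 with a mean under 1 FPKM over the 9 libraries were not tested. No pair of libraries held identical values. Almost all rows have both knockouts on the same side of the control, which can lower p-values by a factor of at most 1.5 for unchanged genes, since 66.7% of them share a side with a common control.

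Values were analysed as log2(FPKM + 1), and a fold change on this scale understates the change of genes with low values. Linear models were fitted with limma 3.58.1 in R 4.3.3 over all 9 libraries, with a mean-dependent prior variance, and tested guide 1 against control, guide 2 against control, the mean of both guides against control, and guide 2 against guide 1. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors of levels are SDs over 3 libraries, and SE refers to the model. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 43 of 51 lists with 3 or more tested genes, and again with an estimated correlation and with fry. No list passed with an estimated correlation, where the lowest adjusted p was 0.412 for the mean of both guides, 0.277 for guide 1, 0.634 for guide 2 and 0.505 between guides. For the mean of both guides 39 passed with fry, which does not compare a list with other genes.

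The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Named genes were those called in both guides with a mean of 5 FPKM or more and all 6 knockout libraries beyond all 3 controls, the 12 largest in each direction by the mean of both fold changes. To these were added the 3 largest in each direction per guide and between guides, and the 2 largest called members of a described list. Predicted genes and pseudogenes by name were passed over. Csmd3 belonged to the rule and was not analysed here. Not all list members that the rule names are reported here.

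The tests were checked on simulated data made from the means and spreads of the 6965 genes, with 200 genes changed. For the mean of both guides, 88.0% of changes of 0.5 log2 units were recovered, 98.5% of changes of 1 and 100% of changes of 2, with 5.88%, 3.43% and 6.54% of calls false. When 1 of 43 lists was shifted, 1 was called. The simulated genes were drawn independently and not selected for a shared side, so this check does not cover lists of correlated genes. Unchanged groups with common controls were simulated 20 times. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, a rescaling by means trimmed by 30% on each side, a replicate block, a constant prior variance, a fold minimum, only the libraries compared, and leaving out each library. Multiplying p-values by 1.5, keeping repeated symbols, dropping genes whose replicates differ over 3 times, and an estimated correlation for the lists between guides were added after seeing the data. Exon overlap was read from the GENCODE annotation of GRCm38 by symbol, with Fisher's exact test in SciPy 1.17.1. Reads shared between a gene and its pseudogenes or overlapping genes could be divided differently between libraries, and Gapdh is left undescribed for that reason.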

Results

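RNA was sequenced from ROC6, a murine oral squamous cell line, in 3 groups of 3 libraries: cells edited with guide 1 against Csmd3, cells edited with guide 2 against Csmd3, and a control without the knockout. Csmd3 encodes a large transmembrane protein with CUB and sushi domains. The series describes the knockouts as separate clones, and its title places them in the study of how loss of the gene alters premalignant oral cells. Expression was given as FPKM, a fragment count scaled to transcript length and to the total of mapped fragments. The sum over uniquely named genes lay between 162625 and 168620 FPKM per library, and 6965 genes with a mean of 1 FPKM or more were tested. Read depth is unknown, because FPKM removes the read total and no counts were used. Within groups, the correlation of log2 values across genes lay between 0.991 and 0.993. It lay between 0.893 and 0.906 for guide 1 with control, between 0.916 and 0.926 for guide 2 with control, and between 0.946 and 0.950 for guide 1 with guide 2. Genes are not independent replicates, so these values carry no p-value.

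Csmd3 itself was not analysed here, so the knockout labels could not be checked against the targeted gene. In 15441 of the 15446 uniquely named rows, the means of both knockouts lay on the same side of the control mean, with 7051 higher and 8390 lower. The 5 other rows had mean values of at most 0.0908 FPKM. Unchanged groups with a common control would share a side in 66.7% of genes. The submitters' name for the deposited values speaks of common differentially expressed genes of knockout against control. A shared direction is therefore a property of the rows analysed here, and counts below are counts among those rows.

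Both knockouts were compared with the control by the mean of the guide groups. A gene can pass this test on 1 guide alone. Tagln passed it (limma adjusted p = 7.71e-10) though guide 2 did not differ from the control (limma adjusted p = 0.13). Counts of list members that rose or fell rest on this mean, and counts called with each guide are given beside them for the lists that passed. The largest shared increases were in S100a4, a calcium-binding protein of motile cells, and Actg2, a smooth muscle actin. S100a4 stood at 2.42 ± 1.07 FPKM (SD, n = 3) in the control, 41.6 ± 3.35 with guide 1 and 214 ± 38.2 with guide 2, which are log2 fold changes of 3.69 and 6.01 (SE 0.212 for each, limma adjusted p = 1.21e-07 and 4.9e-09). Actg2 rose from 7.53 ± 0.789 FPKM to 226 ± 6.32 with guide 1 and 219 ± 3.66 with guide 2, log2 fold changes of 4.74 and 4.70 (SE 0.0627 for each). The largest shared decreases included Slpi, a secreted inhibitor of leukocyte proteases, and Sfrp1, a secreted Wnt antagonist. Slpi fell from 1399 ± 111 FPKM to 40.8 ± 4.84 with guide 1 and 264 ± 29.1 with guide 2, and Sfrp1 from 757 ± 90.7 to 43.5 ± 0.878 and 89.0 ± 2.67.

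Other genes with large shared increases were Il1rl1, a receptor of the interleukin-1 receptor family, the extracellular matrix gene Lama5, Igfbp7, a secreted protein that binds insulin-like growth factors, Ptgs2, the inducible enzyme of prostaglandin synthesis, and Cav1, the main coat protein of caveolae. Il1rl1 rose from 6.38 ± 0.178 FPKM to 71.0 ± 1.59 with guide 1 and 236 ± 7.48 with guide 2. Igfbp7 rose from 34.6 ± 0.303 to 521 ± 25.4 and 170 ± 2.41 FPKM. Ptgs2 rose from 5.10 ± 1.25 to 39.0 ± 2.73 and 54.9 ± 5.55 FPKM, and Cav1 from 6.46 ± 1.09 to 37.4 ± 2.31 and 81.2 ± 0.837 FPKM. Lama5, Olfml2b, Sdc3, Pgf, Prl2c2 and Tspan17 completed the 12 largest, with log2 fold changes against control of 3.95, 4.13, 4.07, 4.82, 3.69 and 4.07 with guide 1 and 1.83, 2.51, 2.08, 1.15, 2.80 and 2.02 with guide 2. One control library of Prl2c2 and one of Tspan17 were listed at 0.

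**Figure D1:**
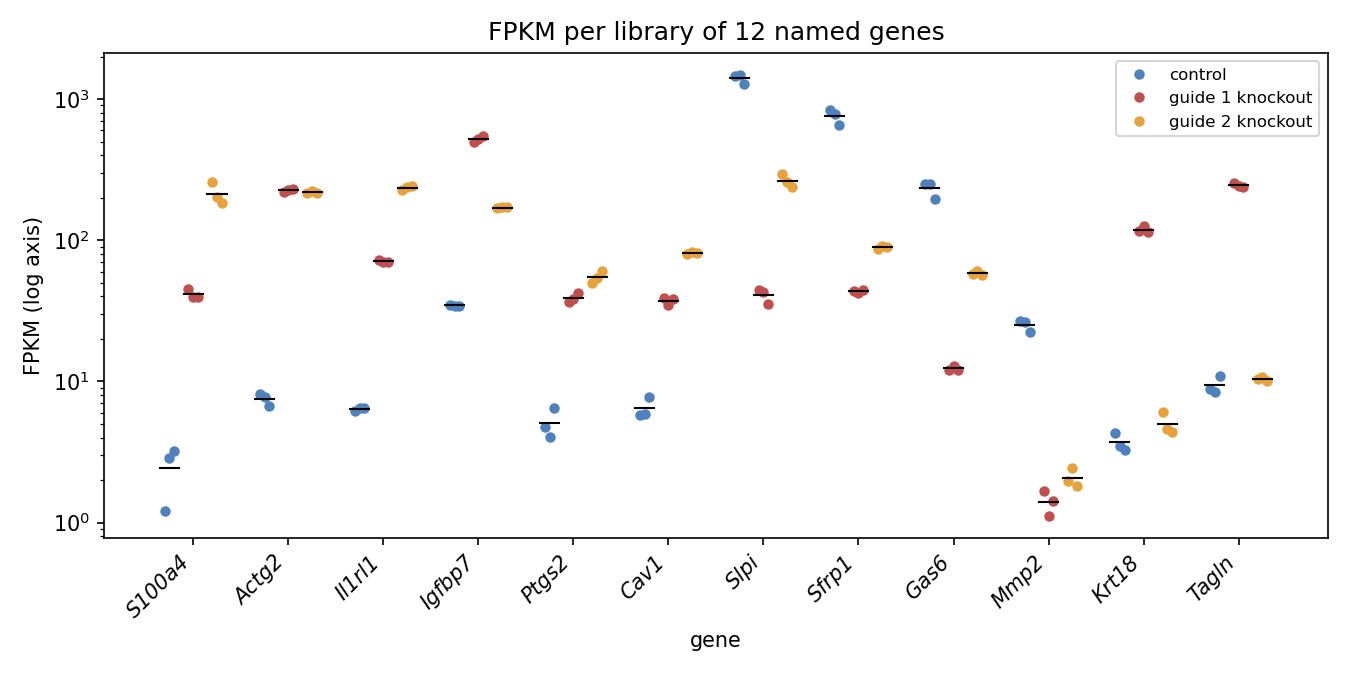
FPKM of 12 named genes in each of the 9 libraries on a log axis, with points for libraries, black lines for the means of 3 libraries, and colours for the control and each knockout. Slpi lies at 1399 FPKM in the control against 40.8 with guide 1 and 264 with guide 2, while Tagln is raised to 246 FPKM with guide 1 and stands at 10.4 with guide 2.

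Among the 12 largest shared decreases, Gas6, a ligand of the Axl receptor family, fell from 233 ± 31.0 FPKM to 12.4 ± 0.461 with guide 1 and 58.3 ± 1.85 with guide 2. Mmp2, a gelatinase, fell from 25.3 ± 2.51 to 1.40 ± 0.278 and 2.08 ± 0.329 FPKM, and Cdh3, the classical P-cadherin, from 14.8 ± 0.667 to 0.369 ± 0.105 and 0.492 ± 0.0474 FPKM. H19, an imprinted noncoding RNA, fell from 15.1 ± 0.686 to 0.384 ± 0.0902 and 0.104 ± 0.0615 FPKM. Eya2, a transcriptional coactivator, stood at 15.3 ± 0.584 FPKM in the control, was listed at 0 in all 3 guide 2 libraries, and was at 0.0736, 0 and 0.0800 FPKM in the guide 1 libraries. Nsg1, Pcsk6, Dhrs9 and Fgf23 also fell, with log2 fold changes of -6.86, -3.69, -3.63 and -4.38 with guide 1 and -2.50, -4.05, -2.99 and -1.93 with guide 2. Igf2, the remaining gene, is described with the differences between guides.

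Over all 6965 genes, 5649 differed from the control in the mean of both guides at a limma adjusted p under 0.05, with 2631 higher and 3018 lower. After trimmed mean rescaling 50.6% of the calls were higher, against 46.6% here, so the excess of lower genes depends on the scaling. Of the 5649, 328 were at least 1 log2 unit higher and 265 at least 1 log2 unit lower. All 6 knockout libraries lay beyond all 3 control libraries in 3738 genes, 53.7% of those tested, where chance gives 2.38%, or 3.57% among rows that share a side. These chance shares take the libraries as exchangeable and say nothing of differences between clones. With the 6 knockout libraries fitted as 1 group, so that the difference between guides counted as spread, 3642 genes passed. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical, and each knockout appears, from the series description, to be 1 clone.

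Genes of cholesterol synthesis were lower in both knockouts. Of 23 tested genes, 22 fell and 1 rose, the same counts when adjusted over the list alone, with a median log2 fold change of -0.62 (camera adjusted p = 6.5e-05). With each guide tested separately, 20 were called lower in both and 0 higher in both. Mvk, which encodes mevalonate kinase, fell from 66.4 ± 3.00 FPKM to 19.9 ± 0.939 with guide 1 and 37.5 ± 1.40 with guide 2. Of 41 listed interferon response genes 16 had a row, so members whose direction differed between guides may be missing. Of 14 tested genes, 14 fell and 0 rose, also when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 0.000918). Of the 14, 11 were called lower with each guide tested separately. Zbp1, a sensor of left-handed nucleic acids, fell by 1.90 with guide 1 and 1.30 with guide 2, and Oasl2 by 1.38 and 0.44, on the log2 scale. With an estimated correlation between genes the adjusted p was 0.545 for cholesterol synthesis and 0.545 for the interferon response.

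The lists of desmosome, matrix, cytoskeleton and mesenchymal transition genes were higher. In this order, 12 of 19, 25 of 40, 29 of 41 and 16 of 26 listed genes had a row. Members whose direction differed between guides may therefore be missing. Genes called higher with each guide tested separately were 5 of 7, 13 of 22, 16 of 27 and 10 of 16. Those called lower with each guide were 0, 6, 3 and 3. All 7 tested desmosome and hemidesmosome genes rose, also when adjusted over the list alone, with a median log2 fold change of 1.16 (camera adjusted p = 0.00141, and adjusted p = 0.483 with an estimated correlation). Pkp2, a desmosomal plaque protein, rose by 2.62 with guide 1 and 1.64 with guide 2, and Pkp1 by 1.38 and 2.30, on the log2 scale. In the extracellular matrix list 16 of 22 tested genes rose and 6 fell, the same when adjusted over the list alone (median 0.88, camera adjusted p = 0.00847, adjusted p = 0.622 with an estimated correlation), led by Lama5 and by Col7a1, the collagen of anchoring fibrils, at 2.26 with guide 1 and 1.33 with guide 2. In the cell migration and cytoskeleton list 18 of 27 rose and 7 fell, against 19 and 7 when adjusted over the list alone (median 0.56, camera adjusted p = 0.00257, adjusted p = 0.545 with an estimated correlation). Myl9, a myosin light chain, rose from 19.2 ± 2.03 FPKM to 135 ± 5.64 and 153 ± 7.74, and Rnd1 rose by 2.19 and 1.58 on the log2 scale. The mesenchymal transition list had 12 of 16 genes higher and 3 lower, the same when adjusted over the list alone (median 0.74, camera adjusted p = 0.00469, adjusted p = 0.545 with an estimated correlation), with Acta2, another smooth muscle actin, rising from 210 ± 4.25 FPKM to 1776 ± 38.3 and 907 ± 11.1. Beside the matrix and mesenchymal lists, 3 of 15 fibroblast markers were tested, of which 2 rose and 1 fell (median 1.08, camera adjusted p = 0.603), with Twist2 at 1.54 with guide 1 and 0.92 with guide 2, and Postn at 0.20 with guide 1, which did not pass (limma adjusted p = 0.19), and 1.96 with guide 2.

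Lists of growth and inflammatory signalling were also higher. For the MYC, NF-kB and EGFR lists, in this order, 18 of 28, 17 of 20 and 15 of 23 listed genes had a row. Here, too, members whose direction differed between guides may be missing. Genes called higher with each guide tested separately were 10 of 17, 7 of 12 and 7 of 12. Those called lower with each guide were 0, 2 and 2. Among MYC targets and ribosome biogenesis genes 15 of 17 rose and 0 fell, and 17 rose when adjusted over the list alone (median 0.41, camera adjusted p = 0.000918, adjusted p = 0.545 with an estimated correlation). Mycl, a MYC family transcription factor, rose by 2.94 with guide 1 and 0.58 with guide 2, and Bop1, a ribosome assembly factor, by 0.73 and 1.04, on the log2 scale. Of the NF-kB targets 10 of 12 rose and 2 fell (median 0.53, camera adjusted p = 0.0276, adjusted p = 0.545 with an estimated correlation). Tnfaip3, a feedback inhibitor of the pathway, rose by 2.81 with guide 1 and 0.85 with guide 2, while Icam1, an adhesion molecule, fell from 4.89 ± 0.390 FPKM to 0.199 ± 0.0375 and 0.0422 ± 0.0116. Of the EGFR ligands and MAPK feedback genes 9 of 12 rose and 3 fell (median 0.86, camera adjusted p = 0.0425, adjusted p = 0.545 with an estimated correlation), with Fosl1 at 2.38 and 1.78 and Dusp5 at 1.77 and 1.39 with guide 1 and guide 2. The counts of these last 2 lists were the same when adjusted over the list alone. The EGFR list did not pass after quantile normalization or trimmed mean rescaling, where its highest adjusted p over the alternatives was 0.0545.

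Immediate early genes, fixed as a sign of handling and sample quality, were higher beside these signalling lists. With each guide tested separately, 8 of 11 were called higher in both and 0 lower in both. Of 11 tested genes 9 rose and 1 fell, also when adjusted over the list alone (median 0.80, camera adjusted p = 0.00257, adjusted p = 0.412 with an estimated correlation), with Egr1 rising by 1.18 with guide 1 and 2.21 with guide 2, and Nr4a1 by 1.61 and 1.68. Of 7 heat shock genes, another such sign, 5 rose and 2 fell (median 0.20, camera adjusted p = 0.192), with Hspa1b at 0.97 and 2.88 and Hspa1a at 0.62 and 1.93 with guide 1 and guide 2. Replication-dependent histones, also fixed for quality, had 2 of 3 tested genes higher and 1 lower (median 1.89, camera adjusted p = 0.145). H1f2 rose by 2.50 and 2.56, and H2bc4 by 2.48 and 1.30. In the last such list, cytosolic ribosomal proteins, 9 of 30 rose and 9 fell (camera adjusted p = 0.892).

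**Figure D2:**
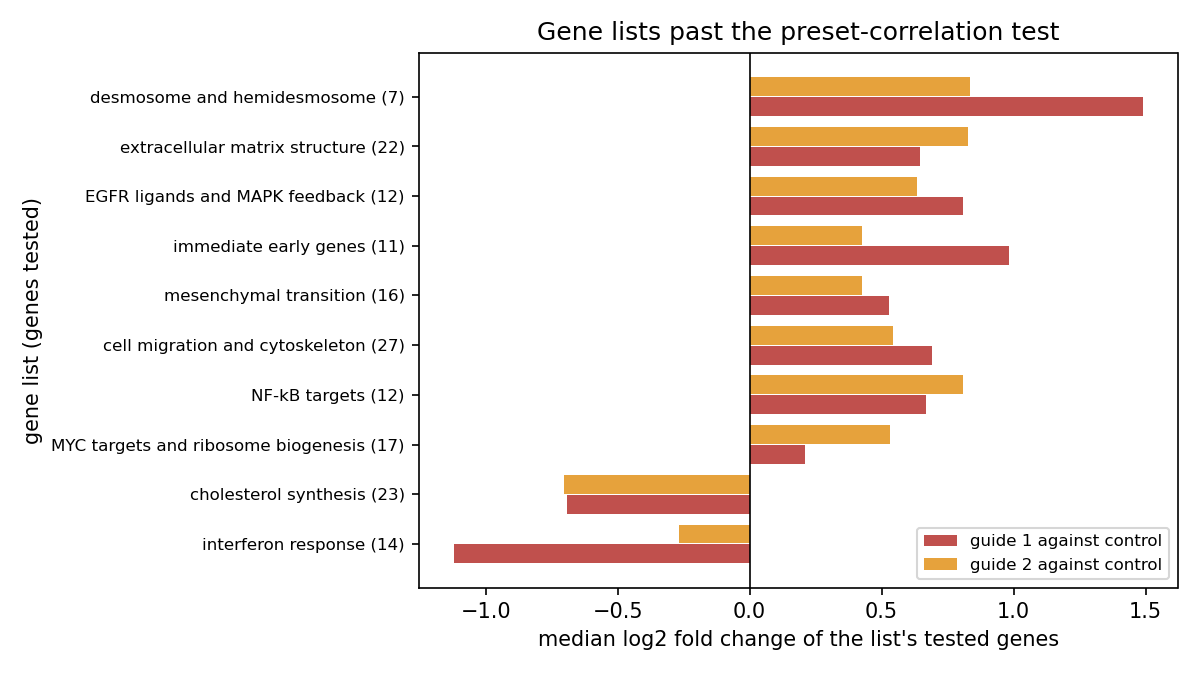
Median log2 fold change against control of the tested genes in the 10 gene lists that passed the preset-correlation test, with a bar for guide 1 and a bar for guide 2 and the number of tested genes in brackets. Cholesterol synthesis has medians of -0.69 and -0.70, and the interferon response medians of -1.12 and -0.27.

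The other 33 of the 43 lists with 3 or more tested genes did not pass. The cell cycle lists went both ways or moved little: 11 of 22 genes of G1/S and DNA replication were higher and 8 lower (median 0.10, camera adjusted p = 0.355), and 2 of 13 genes of G2/M and mitosis were higher and 9 lower (median -0.22, camera adjusted p = 0.140). Of 26 respiratory chain genes 18 were lower and 4 higher (median -0.25, camera adjusted p = 0.0529). The epithelial junction list had 3 of 5 tested genes higher and 2 lower, and its median of 0.85 and mean of -0.24 differed in sign (camera adjusted p = 0.752). Among markers of other cell types, besides the fibroblast genes, 1 of 24 leukocyte genes was tested and rose by 0.72 on the log2 scale. Of 14 markers of salivary and simple glandular epithelium, 1 was tested and rose by 1.98. Of 13 muscle genes, 1 was tested and fell by 0.64, and it was called with guide 2 but not with guide 1. Each passed for the mean of both guides (limma adjusted p under 0.05). Only 5 of 14 endothelial markers and 6 of 16 melanocyte, neural and Schwann markers had a row, and none of them passed the filter on low values. Markers without a row say nothing of expression.

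Against the control, guide 1 alone changed 4745 genes, 2106 higher and 2639 lower, of which 396 and 331 differed by at least 1 log2 unit. The share of higher genes, 44.4%, was 50.4% after trimmed mean rescaling. The largest increases were in Pgf, a placental growth factor, Actg2, and Krt18, a keratin of simple epithelia. Krt18 rose from 3.70 ± 0.561 FPKM to 119 ± 6.56 (log2 fold change 4.68, SE 0.110, limma adjusted p = 2.25e-10). Pgf rose from 0.450 ± 0.0901 to 39.8 ± 0.381 FPKM. Nsg1, a neuronal endosomal protein, fell from 144 ± 10.2 to 0.246 ± 0.109 FPKM, followed by Slpi and by Fgf23, a hormone of phosphate balance, which fell from 23.4 ± 2.14 to 0.171 ± 0.0836 FPKM.

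Against the control, guide 2 alone changed 4557 genes, 2223 higher and 2334 lower, of which 280 and 288 differed by at least 1 log2 unit. The share of higher genes, 48.8%, was 51.7% after trimmed mean rescaling. S100a4, Il1rl1 and Actg2 had the largest increases. Igf2, a fetal growth factor, stood at 45.7, 46.0 and 38.2 FPKM in the control libraries, at 18.8, 18.0 and 20.2 with guide 1, and at 0.0374, 0 and 0.0244 with guide 2. Pcsk6, a proprotein convertase, fell from 19.5 ± 1.39 to 0.232 ± 0.0788 FPKM, and Eya2 was listed at 0.

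Guide 1 and guide 2 shared 3403 called genes with the same direction, 1576 higher and 1827 lower, and 0 with opposite directions. Lists of these sizes, independent in direction as well as in calls, would share 672 and 884. All 6965 tested genes share a side by mean FPKM, so this expectation is too low for these rows. Unchanged groups simulated against the same controls shared a mean of 0.05 genes. Across genes, Pearson's r of the fold changes was 0.737 and the covariance 0.340. Simulated unchanged groups gave an r of 0.486 and a covariance of 0.00675, or 0.756 and 0.0125 when only genes with a shared side were kept. The observed correlation was thus no higher than that of unchanged genes selected for a shared side, and the overlap, its direction and the correlation cannot be separated from how the rows were chosen. The 3 controls do not give each guide 2 of its own, so part of the excess over independent lists may also come from the shared controls.

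**Figure D3:**
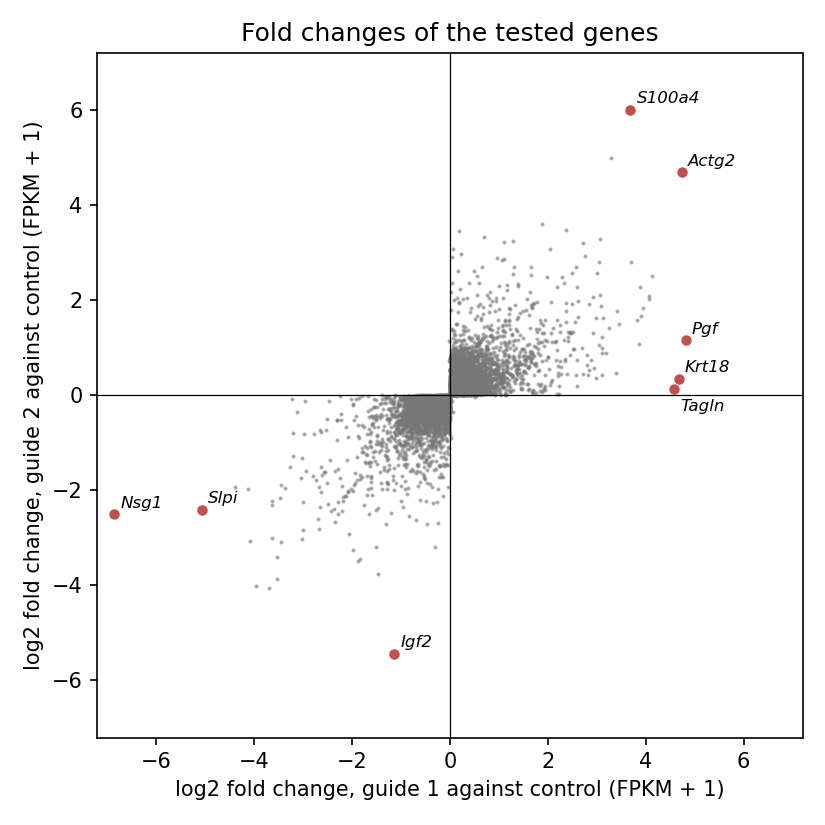
Log2 fold change against control with guide 1 on the horizontal axis and with guide 2 on the vertical axis, 1 point for each of the 6965 tested genes, with 8 named genes in red. Points fill the quadrants in which both knockouts have the same sign, and across genes r was 0.737.

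Between the knockouts, 3793 genes differed, 2170 higher with guide 2 and 1623 lower, a test in which the control cancels. The balance turned at 1 log2 unit, with 160 higher and 189 lower, and the share of higher genes, 57.2%, was 52.5% after trimmed mean rescaling. Tagln, an actin-binding protein of smooth muscle, stood at 246 ± 6.88 FPKM with guide 1, 10.4 ± 0.303 with guide 2 and 9.43 ± 1.31 in the control, a difference of -4.43 log2 units between guides (SE 0.0768, limma adjusted p = 1.38e-10). Krt18 stood at 119 ± 6.56 FPKM with guide 1 and 5.01 ± 0.910 with guide 2. Tnn, a matrix protein of the tenascin family, was at 0.102 ± 0.0164 FPKM with guide 1, 8.77 ± 1.17 with guide 2 and 9.25 ± 0.193 in the control, and Smpdl3b, a lipid-modifying phosphodiesterase, at 2.24 ± 0.557, 22.1 ± 0.916 and 23.9 ± 1.92. Of the 3403 shared calls, 2010 also differed in size between the guides, 1172 larger with guide 1 and 838 larger with guide 2. Interferon response genes were less reduced with guide 2, with a median difference of 0.63 log2 units (camera adjusted p = 0.000348, adjusted p = 0.717 with an estimated correlation), and the TGF-beta and BMP list was lower with guide 2, with a median difference of -0.47 (camera adjusted p = 0.000249, adjusted p = 0.505 with an estimated correlation).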

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

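The tests of row selection on the whole table, of row selection and clone differences for the single lists, the comparison of gaps by list and the value for a fixed control were chosen after the results were seen. The knockouts differed from each other in 3793 genes, and the following named genes were singled out because the test of guide 2 against guide 1 passed (limma, adjusted p under 0.05). Differences of guide 2 minus guide 1, in log2 units, were 2.32 for S100a4, 1.72 for Il1rl1, 0.48 for Ptgs2 and 1.10 for Cav1 among genes raised in both, and -1.62 for Olfml2b, -0.89 for Prl2c2, -1.99 for Sdc3, -1.61 for Igfbp7, -2.05 for Tspan17, -3.66 for Pgf and -2.12 for Lama5. Among genes lowered in both they were 4.36 for Nsg1, 2.66 for Slpi, 1.02 for Sfrp1, 0.64 for Dhrs9, 0.36 for Mmp2, 2.45 for Fgf23 and 2.15 for Gas6, and -0.36 for Pcsk6, -0.33 for H19 and -4.29 for Igf2. Genes named for the contrast between guides were Krt18 at -4.33, Tagln at -4.43, Tnn at 3.14 and Smpdl3b at 2.85. As lists, median differences were -0.66 for desmosome and hemidesmosome, -0.47 for TGF-beta and BMP signalling, 0.63 for interferon response and -0.17 for lysosome and autophagy (camera adjusted p = 0.0157, 0.000249, 0.000348 and 0.0495), and adjusted p = 0.505, 0.505, 0.717 and 0.877 with an estimated correlation.

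Both knockouts lay on the same side of the control in 15441 of 15446 genes. A candidate explanation is that rows were kept for a shared direction. The submitters' name for the deposited values, which speaks of common differentially expressed genes, points the same way but gives no rule. Of 103 genes with an unadjusted p above 0.5 in both guide comparisons, 103 (100%) shared a side by mean FPKM, and 97 by mean log2 value. The share by mean log2 value was seen first and left the explanation undecided by the bound set for it, and mean FPKM was used after that. Since all 6965 tested genes share a side by mean FPKM, the 100% was fixed in advance and adds nothing. Simulated unchanged groups with common controls shared a side in 65.9% to 67.5% of genes. The share over all rows, and the 97 of 103 genes by mean log2 value, lie far above that. These values argue for rows kept for a shared direction, and the rule by which they were kept was not tested. If 3 unrelated lines without a shared knockout effect were selected in this way, the gap from the control to the nearer knockout would exceed the gap between knockouts in 50% of genes, and if each knockout differed on its own from a fixed control, in 41.0%. The observed share was 45.8%, and 46% to 50% with 1 library left out, not above the value for unrelated lines and above that for a fixed control, so it neither shows nor excludes an effect common to both knockouts. An effect of the knockout stays open, since what appears to be 1 clone per guide cannot tell it from differences between clones.

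Cholesterol synthesis and interferon response genes were lower in both knockouts. A shift of the library scale is argued against by the medians after quantile normalization, -0.60 for cholesterol synthesis and -0.73 for the interferon response. Row selection can have removed little of the cholesterol list, of which 95.8% of genes had a row analysed here, but stays open for the interferon list with 39.0%. The ratio of the median gap to the control to the median gap between knockouts was 0.426 for the interferon response and 2.78 for cholesterol synthesis (2.40 to 3.17 without 1 library). A ratio below 1 had been set as the mark of clone differences, and the interferon list met it. A shared effect of unequal size could give it too, and the ratio over all tested genes was 0.825. The interferon value therefore does not separate clone differences from the knockout. A ratio above 1 had been set as the bound against clone differences, but 17 of 43 lists exceeded it and cholesterol synthesis ranked 3, so clone differences and the knockout cannot be told apart for that list.

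In 37 of 4646 genes with a mean of 5 FPKM or more, replicates of a group differed over 3 times, and 21 of the 37 carry predicted or pseudogene names. Overlap with exons of another gene was 38.9% among them and 35.8% among other genes (Fisher's exact p = 0.729), and their median FPKM was 0.869 times that of the others, so neither division of fragments between overlapping records nor low expression was decided. Prl2c2, Tspan17, Eya2, H19, Igf2 and Fgf23 are among the 37, each with a group near 0.

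For chance as the source of the counts, the real grouping gave 4745 genes for guide 1, 4557 for guide 2 and 3793 between guides, against highest other values of 1, 0 and 2. In each, 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Of 100 drawn splits of the 9 libraries, 1, the real one, reached 5649 genes for both guides (highest other 3514), and 1, the real one, reached 3403 shared calls (highest other 2229). All tested rows share a side under the real grouping, which favours it among the splits. Simulated unchanged groups kept for a shared side had an unadjusted limma p under 0.05 for both guides in 7.54% of genes (highest 8.42%), against 82.7% observed, and gave at most 1 call for both guides and at most 1 shared call. Chance spread between libraries, as simulated, therefore does not account for as many as 5649 calls for both guides or 3403 shared calls. Single calls among them may still be false. The shared calls are part of the counts of guide 1 and of guide 2, so the same holds for that part of each. For the 1342 genes called with guide 1 only and the 1154 with guide 2 only, the splits leave chance undecided. They also leave it undecided for the calls between guides. No kept-side calls were simulated for either guide alone or between guides. None of this speaks of differences between clones, cultures or batches, or of handling. For the 10 gene lists, 18 of 100 splits gave as many (highest other 14), so chance cannot be excluded for the number of lists. That number was 18 without control replicate 1 and 16 without control replicate 2.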

How the results depend on the processing

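The alternatives with p-values times 1.5, with repeated symbols kept, without genes whose replicates differ over 3 times and with an estimated correlation between guides were chosen after seeing the data. For the mean of both guides, all 1809 values of the 102 genes named by the rule kept their direction and side of the threshold. These values cannot include the minimum of 1 log2 unit, which named genes such as Bop1, at 0.88, would not pass. Requiring a difference of 1 log2 unit lowered the counts, by construction, to 727 for guide 1, 568 for guide 2, 593 for both guides, 349 between guides and 297 shared calls. The 6 knockout libraries as 1 group gave 3642 genes for both guides, since the difference between guides then adds to the spread. The correlation of fold changes was 0.752 with a filter of 5 FPKM and 0.715 with repeated symbols kept. The number of lists was 24 with no filter on low values, 0 with an estimated correlation and 39 with fry, and leaving out 1 library gave 10 to 18 lists, and the causes were not tested. Between guides 4 lists passed, and 0 with an estimated correlation. Leaving out 1 library gave 4438 to 4805 genes for guide 1, 4212 to 4508 for guide 2, 5186 to 5615 for both guides, 3375 to 3885 between guides and 3054 to 3400 shared calls. With p-values times 1.5 the counts were 4532, 4332, 5422 and 3562. A replicate block gave 4764, 4559, 5651 and 3784 genes, 3424 shared calls and 10 lists. Of 9 same-numbered pairs of libraries, 2 had a correlation of deviations over 0.1, in a range of -0.107 to 0.245. Between the knockouts the same-numbered values were 0.245, 0.0219 and 0.21, and the other values lay between -0.234 and 0.0423. Same-numbered values of a knockout with the control were at most 0.0556. Since 7 of 9 libraries correlated best with their own number, a batch by replicate number shared by the knockouts is not excluded. Depth is unknown, so no limit from counting can be given for low genes.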

Other observations

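The tests of contractile and imprinted genes were chosen after the genes that drew attention to them were seen. Other fixed lists did not pass as lists but held large single changes. Of 10 tested angiogenesis factors 7 rose and 3 fell (median log2 fold change 1.07, camera adjusted p = 0.0529). Vegfd, a lymphatic growth factor, fell from 26.2 ± 5.37 FPKM (SD, n = 3) in the control to 1.44 ± 0.506 with guide 1 and 5.00 ± 0.225 with guide 2. Of 13 apoptosis regulators 4 rose and 6 fell (median -0.14, camera adjusted p = 0.804), and Ripk3, a kinase of necroptosis, fell from 11.9 ± 0.514 FPKM to 1.65 ± 0.275 and 1.71 ± 0.225. Of 11 YAP and TEAD targets 8 rose and 2 fell (median 0.23, camera adjusted p = 0.0529), and Igfbp3, a binding protein of insulin-like growth factors, rose from 0.866 ± 0.118 FPKM to 10.1 ± 0.642 and 11.1 ± 1.04. Of 12 MHC class I genes 4 rose and 8 fell (median -0.34, camera adjusted p = 0.426). Psmb8, an immunoproteasome subunit, fell from 13.9 ± 0.330 FPKM to 1.17 ± 0.105 with guide 1 and 7.51 ± 0.316 with guide 2.

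Acta2, Actg2, Myl9 and Tagln led to the hypothesis that contractile genes dependent on serum response factor may be raised together. A list of such genes written from general knowledge, without those 4, had 31 tested genes, of which 29 rose and 2 fell, with a median log2 fold change of 0.75 (camera p = 4.59e-11, adjusted over the pair of lists 9.18e-11, and p = 0.0131 with an estimated correlation). Of the 31, 8 also belong to the lists fixed earlier. The ratio of the gap to the control to the gap between knockouts was 1.16, so this pattern, too, is not separated from differences between clones. H19 and Igf2 led to the hypothesis that imprinted genes may be lowered together. Without them, 4 imprinted genes were tested, 2 higher and 2 lower. For this list limma's camera gave an adjusted p = 0.792 over the pair of lists, and so few genes do not decide the hypothesis. By the bound written for this test, a camera p of 0.05 or more, the hypothesis would have been rejected, and that reading was set aside after the value was seen because of the 4 genes.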
